A study of Drosophila melanogaster with 2 samples.

How the data were processed

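The samples were 2 libraries of anti-GFP chromatin immunoprecipitation from Drosophila melanogaster embryos that express Bteb2-eGFP, in 1 group, with replicate numbers 1 and 3 taken from the labels, which call them biological replicates. The labels do not say how the embryo collections were kept apart, so differences between the 2 libraries may be partly technical. No test was made over the replicates: tests ran over peaks, windows or genes. The age field of the labels holds a damaged number, and the age of 4 to 20 h is that of the source name. A control is named in the labels as a possible one, and no control sample was analysed here.

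The authors' deposited files used here were peak lists on the dm6 and dm3 builds, per the labels and the notes beside the files. For each build these were a relaxed list for each replicate, a relaxed list for the pooled replicates, and an optimal set kept by the irreproducible discovery rate method from these lists. Per those notes, each relaxed list was made by the authors from alignments and 1 further file common to both replicates. The aligner, the peak caller, the duplicate filter and the threshold of the optimal set are not given in the sources used here. The deposited lists have no header and follow the narrowPeak column order. In that order the authors' signal value of a peak is column 7, and its scale differs between lists, so signal was used to rank peaks within a list only. The −log10 q-value is that of the authors' peak caller, in the deposited column 9, and saturates at the top of each list. Of the optimal peaks 83.9% were 416 bp wide, within a range of 104 to 498 bp.

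All coordinates are on dm6 and 1-based. The genome was the Release 6 assembly, whose chromosome names and lengths hold all dm6 peaks, and the annotation that of Ensembl release 115 (FlyBase 6.54), with 18277 genes, of which 13968 are protein-coding, and 23694 distinct TSS positions. Transposable elements were left out. All dm6 summits lay on the arms 2L, 2R, 3L, 3R, 4, X and Y. Analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with random seed 20.

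Choices named in this section as main were fixed before the data were examined. Comparison peaks were the lower-ranked 15000 of the 30000 pooled relaxed peaks, without the 305 that share at least 1 bp with an optimal peak, which left 14695. They come from the same libraries and the same mappable genome. The authors' own name for the relaxed lists is peaks and background, and the −log10 q-value of the pooled list fell to 0.180. Comparison peaks may therefore include background regions, and how many was not determined. A summit counted as promoter when it lay within 1000 bp of any TSS, and other summits were classed in the order coding exon, 5′ UTR, 3′ UTR, noncoding exon, intron, intergenic. Shares were compared with two-sided Fisher's exact tests, with the sample odds ratio and its Woolf 95% interval, and shares of a single set carry exact Clopper-Pearson intervals. Replicates were compared by the share of the 3350 highest-signal peaks of each that overlap by at least 1 bp, with 1000 circular shifts along the arms.

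Motifs were searched on both strands in windows of 201 bp around the summit, 24 of them fixed in advance, and in flanking windows 500 bp away by exact McNemar tests. All 2080 six-base words, with reverse complements merged, were tested in the same way. A gene had a peak when an optimal summit lay within 1000 bp of any of its TSSs, and 28 gene lists of 8 to 306 members were tested against the other protein-coding genes, or all other genes for the lists of RNA genes. Of the listed symbols 4 were brought up to date through synonyms (Pyk to PyK, h to hry, svb to ovo, and CG9895, which merged with CG42741). P values were adjusted by the Benjamini-Hochberg method within each family of 24 motifs, 2080 words, 28 lists or 7 location classes (6 over distal summits), at a threshold of 0.05. The X was compared with the arms of chromosomes 2 and 3 by an exact binomial test on length.

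Named genes followed a fixed rule. They are the gene with the nearest TSS at each of the 25 strongest optimal peaks, every member of the KLF and SP list, and up to 4 members of each other list with the strongest promoter peaks. Words named are the 10 of highest odds ratio among those past the threshold and in at least 5% of optimal windows. Neighbours that share a peak are named with it for the strongest 25. GGAGGA and the genes named in the closing section for their number of peaks or as divergent pairs were chosen after their values were seen.

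The tests were tried on simulated data. In a random division of the comparison windows into 3350 and 11345, none of the 24 motifs and none of the 2080 words were called. Unlike the optimal and comparison sets, the parts of such a division do not differ in GC content or promoter share beyond chance. The trial therefore cannot show calls that come from those differences. With 4 motifs added to 4% of the 3350 windows, all 4 were called and none of the other 20. With peaks at 3350 random TSSs, 1 of 28 lists was called, that of small nucleolar and nuclear RNA genes, whose members lie close together or within other genes, so tests of that list count neighbours as independent. A list given 30 added peaks, the proteasome, was called.

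Alternatives fixed in advance were the dm3 lists, the stronger 50% of the optimal peaks, other overlap rules (summits within 100 bp, 50% reciprocal overlap, and the strongest 500, 1000, 2000 and 5000 peaks), other distances to a TSS (250, 500 and 2000 bp), protein-coding TSSs, the nearest TSS only, random positions, the next-ranked pooled peaks (ranks 3351 to 6700, of which 3144 were used), windows of 50 and 200 bp to each side, comparison windows matched on GC content in bins of 2%, flanking and dinucleotide-shuffled windows, the CACCC-type and GC box alone, 10000 random gene lists matched on gene length and number of TSSs, other bases for the arms, and each replicate left out. Leaving out a replicate means using the 3350 strongest peaks of the other, with the lower-ranked part of its own list as comparison. Random lists were drawn within classes of gene length and number of TSSs, and p values from them are called permutation. The odds ratio beside them sets members with a peak against the mean of the draws, with a small constant added to each count. Windows within 500 bp of a TSS, these matched on GC content, and genes with any relaxed promoter peak as background were added after the data had been seen. Alignments, coverage tracks and controls were not used here.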

Results

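The series measured where a tagged transcription factor sits on DNA in the embryo of the fruit fly Drosophila melanogaster. Chromatin immunoprecipitation followed by sequencing was carried out with an antibody against green fluorescent protein (GFP) on transgenic flies that carry Bteb2 fused to enhanced GFP. Bteb2 is the product of Klf15, a member of the KLF family of zinc finger proteins, which bind GC-rich and CACCC-type boxes. Embryos of both sexes were collected at 4 to 20 h, and chromatin was sonicated to 200 to 800 bp. The samples form 1 group of 2 libraries, which the labels call biological replicates 1 and 3. With 1 group there was no contrast between conditions. The comparisons below set the authors' reproducible peaks against weaker candidate regions of the same libraries, against the genome, and replicate against replicate. These weaker regions may include background, so a contrast with them need not be one of strong against weak binding.

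The anti-GFP libraries gave 3350 reproducible regions on dm6, called here the optimal peaks. Peaks were called by the authors in each replicate and on the pooled replicates, with 30000 candidate (relaxed) peaks in each list. The optimal peaks were exactly the 3350 pooled peaks of highest signal, and the same held for the 3696 optimal peaks on dm3. The peak score is the authors', and ranks from lists of different lengths show no change. The median signal of the optimal peaks was 98.8, with quartiles of 78.6 and 145 and a range of 65.9 to 1369. Every optimal peak had the same −log10 q-value of 3.95, the highest in the list, so signal alone ranked them. Reads per library were not analysed here, so the depth is unknown. Controls and anti-GFP peak lists of other tagged factors were not analysed here either, so sites of Bteb2-eGFP were not told apart from regions that many such experiments recover, and this limit holds for each result on promoters, motifs and gene lists.

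The replicates recovered largely the same regions. Of the 3350 strongest peaks of replicate 1, 2522 shared at least 1 bp with the 3350 strongest of replicate 3, or 75.3% (exact 95% interval 73.8 to 76.7). In the other direction the share was 74.4% (72.9 to 75.9). Peaks shifted along their chromosome arms overlapped at 1.87% on average and at most 2.96% in 1000 shifts, which gave a permutation p of 0.001, the smallest that number of shifts allows. The shifts did not keep peaks at promoters, so this p does not tell shared promoter regions from shared sites of the factor. The overlap was 67.3% when summits had to lie within 100 bp of each other. Of the optimal peaks, 3345 were found in both relaxed lists and 2493 among the strongest 3350 of both replicates, while 498 were so ranked in replicate 1 alone, 336 in replicate 3 alone and 23 in neither. The optimal set was kept for reproducibility from these lists, so this agreement is partly built in. The signals of the replicates had a Spearman rho of 0.681 across the optimal peaks found in both, which are regions and not independent replicates.

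The optimal peaks lay mostly at promoters. Of the 3350 optimal summits, 2294 (68.5%) fell within 1000 bp of an annotated transcription start site (TSS). Of the 14695 comparison summits, the lower-ranked regions of the pooled list, 5512 did (37.5%). The odds ratio was 3.62 (95% interval 3.34 to 3.92, two-sided Fisher's exact test p = 1.08e-233). Positions spread evenly over each arm would give 23.7%. The ratio was 3.76 in the peaks of replicate 1 alone and 4.04 in those of replicate 3 alone. Against the next-ranked pooled peaks it was 1.37 (1.24 to 1.52), since 61.3% of those also lay within 1000 bp of a TSS. The median distance to a TSS was 264.5 bp for optimal summits and 1637 bp for comparison summits. Within 250 bp the shares were 49.4% and 14.9%. Of the 2294 promoter summits, 1778 (77.5%) lay upstream of the nearest TSS, and the median position of all 2294 was -90 bp. The side of the TSS was not determined for comparison summits.

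Outside promoters the optimal summits lay mainly in introns and almost never in coding exons. Of the 1056 optimal summits over 1000 bp from a TSS, 786 (74.4%) were intronic against 59.5% of the 9183 such comparison summits, an odds ratio of 1.98 (1.72 to 2.29, exact adjusted p = 1.42e-21). Coding exons held 4 (0.379%) against 11.4% (odds ratio 0.0294, 0.0110 to 0.0787, exact adjusted p = 2.53e-45), and 3′ UTRs 2.27% against 7.21% (odds ratio 0.299, exact adjusted p = 2.34e-11). Intergenic sequence (21.4% against 20.6%), 5′ UTRs and noncoding exons did not pass. These Fisher's exact tests over distal summits were chosen after the data had been seen. Over all summits, where the promoter class takes up the larger part, introns held 23.5% of optimal against 37.2% of comparison summits (odds ratio 0.518, exact adjusted p = 3.58e-53) and intergenic sequence 6.75% against 12.9%. Tests over peaks or genes treat them as independent, and intervals cover counting error only.

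**Figure D1:**
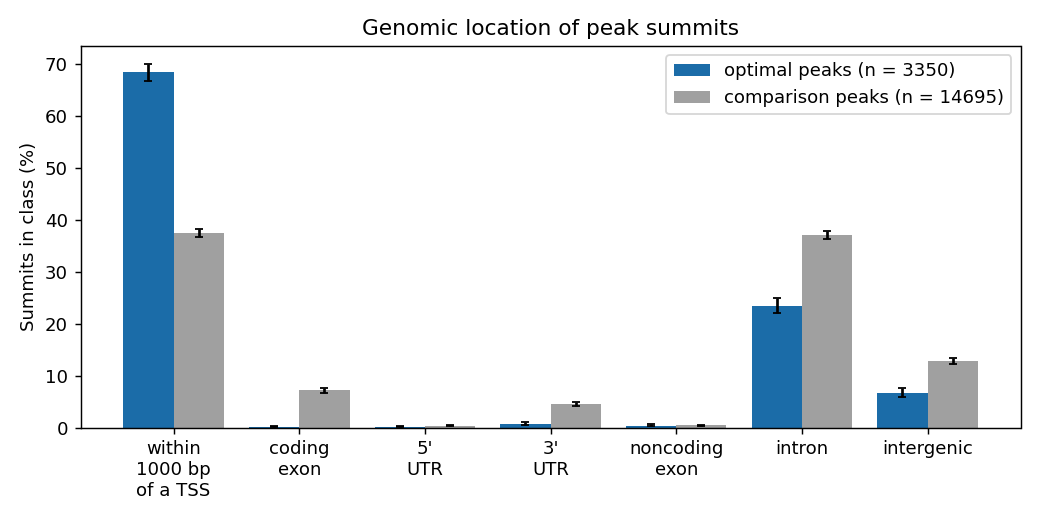
Share of summits (percent, vertical axis) in each annotation class for 3350 optimal peaks (blue) and 14695 comparison peaks (grey), with exact 95% binomial intervals as error bars. The promoter class holds 68.5% of optimal and 37.5% of comparison summits, and coding exons 0.119% and 7.15%.

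The strongest optimal peaks lay near CG11050, CG14100, cbt, Lk6, mRpL41 and Ugalt. The highest signal, 1369, was at 2L from 6612465 to 6612915 on dm6, in an intron of CG11050 (1013 bp downstream of its TSS), and the next, 1306, at 3L from 19590433 to 19590814, 92 bp upstream of CG14100. The peak of rank 3 (signal 1155, 2L from 480868 to 481284) lay 1370 bp upstream of cbt, which encodes the KLF-type zinc finger protein Cabut, in an intron of ush, which encodes a zinc finger cofactor of GATA proteins. Rank 4 (signal 1056, 3R from 11760862 to 11761229) was 976 bp upstream of the nearest TSS of Lk6, a protein kinase gene. Rank 5 (signal 1026, 2R from 15217573 to 15217935) was 139 bp upstream of mRpL41, a mitochondrial ribosomal protein gene that shared the peak with CG8079 and lncRNA:CR44463. Rank 6 (signal 992, X from 2703704 to 2704071) was 42 bp upstream of Ugalt, a UDP-galactose transporter gene, and also within 1000 bp of eIF2Bbeta. These 6 peaks ranked between 1 and 6 in both replicates.

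The nearest TSS of the other peaks among the strongest 25 belonged to px, Chro, Art3, PNPase, CenG1A, CG31145, CG1888, Tcs5, CG32772, gish, larp, HmgZ, GstE13, CG9147, ph-p, Fkbp14, Trl and, at 2 peaks, lncRNA:CR44619. Chro (rank 9, 3L from 22878708 to 22879098) encodes the chromodomain protein Chromator, and its promoter peak was shared with Ssl1, a gene of the general transcription factor TFIIH. ph-p (rank 22, X from 2137199 to 2137519, 471 bp upstream of the nearest TSS) encodes a Polycomb group protein. Trl (rank 24, 3L from 14759330 to 14759714, in an intron) encodes GAGA factor. Art3 shared its peak with mRpS10, PNPase with Gprk2, CenG1A with mRpS23, Tcs5 with CHMP2B and CG9147 with Fbw5. Of these 25 peaks, 4 lay over 1000 bp from a TSS, namely those of CG11050, cbt, CG32772 and Trl, all in introns.

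Among the 10 annotated genes of the KLF and SP family, cbt alone had an optimal peak within 1000 bp of a TSS (signal 331, rank 131, 2L from 479914 to 480193, 392 bp from the TSS). The other members, Klf15, luna, dar1, Spps, Sp1, btd, hkb, CG3065 and CG42741, had none. At Klf15 itself (X from 4770557 to 4771588), the gene whose product was tagged, the nearest optimal summit lay 9078 bp from the TSS, in intergenic sequence (X from 4762302 to 4762717). The pooled relaxed list held weaker peaks within 1000 bp of a TSS of Spps, CG3065, CG42741, dar1, btd, luna and hkb, the highest at rank 3827 of 30000 for Spps, and none at Klf15 or Sp1. The share of 1 in 10 did not differ from the 20.4% of other protein-coding genes (odds ratio 0.434, 0.0549 to 3.42, Fisher's exact test adjusted p = 0.857).

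The KLF/SP site GGGYGKG, which covers the boxes bound by KLF and SP zinc fingers, was less frequent at optimal than at comparison summits. It occurred in 127 of 3350 windows of 201 bp (3.79%) against 1174 of 14695 (7.99%), an odds ratio of 0.454 (0.376 to 0.547, two-sided Fisher's exact test adjusted p = 1.04e-18 over 24 motifs). The ratio was 0.212 (0.126 to 0.357) for the CACCC-type box alone and 0.276 (0.121 to 0.630) for the GC box alone. These boxes were rare, in 0.448% and 0.179% of optimal against 2.08% and 0.646% of comparison windows. They were not tested with equal GC content. The ratio of GGGYGKG was 0.486 in the peaks of replicate 1 alone and 0.442 in those of replicate 3 alone. Against the next-ranked pooled peaks it was 0.725 (0.572 to 0.920, exact adjusted p = 0.0483). Windows 500 bp to either side of the same summits held the site at 9.31% on the left and 9.31% on the right (exact McNemar test, adjusted p = 7.48e-19 and 5.85e-19). Those flanking windows were not matched on GC content. Optimal summits were poor in G and C, with a GC content of 36.1% ± 6.62 (SD, 3350 windows) against 41.3% ± 9.21 (SD, 14695 windows). Against comparison windows of the same GC content the difference did not pass (3.79% against 4.72%, odds ratio 0.796, 0.627 to 1.01, exact p = 0.0692). The site was more frequent than in shuffles of the optimal windows that kept dinucleotides (3.79% against 2.48%, odds ratio 1.55, unpaired Fisher's exact test p = 0.00249). Comparison windows were not shuffled, so this excess may not be particular to optimal peaks.

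**Figure D2:**
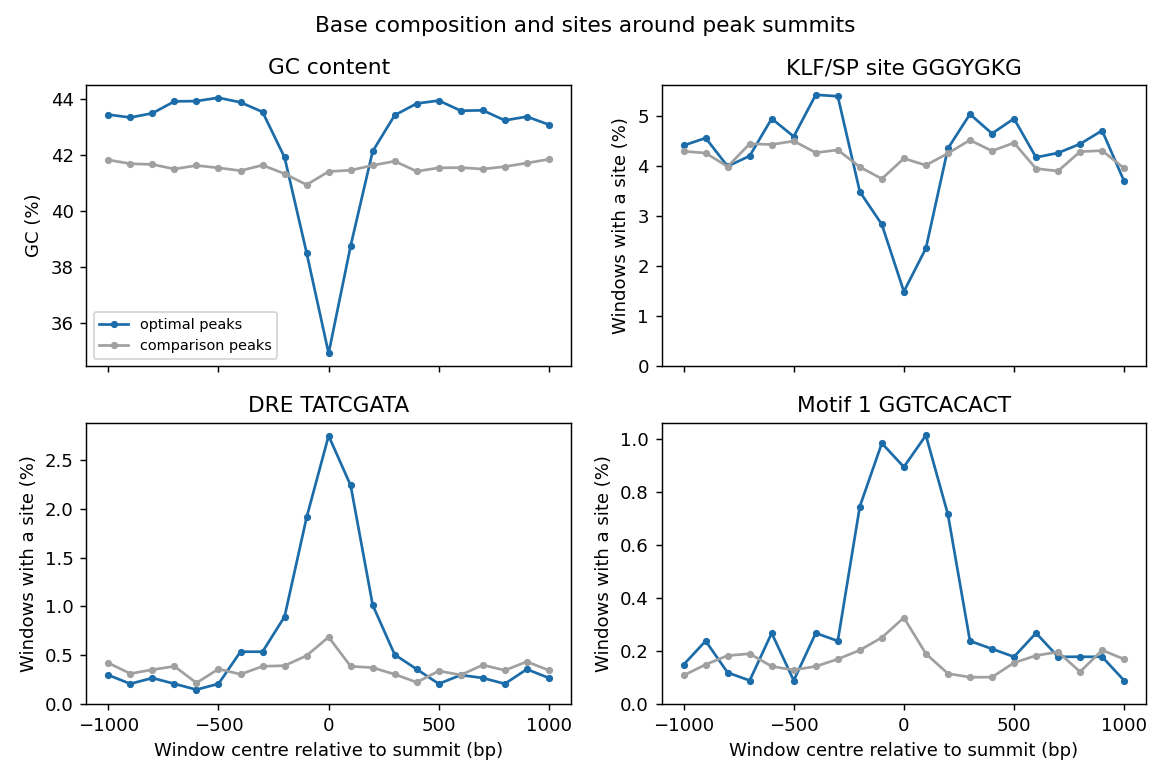
GC content and the share of windows with a KLF/SP site, a DRE and a motif 1 site (percent, vertical axes) in windows of 101 bp centred from -1000 to 1000 bp of the summit (horizontal axes), for optimal (blue) and comparison (grey) peaks. At the optimal summit GC falls to 34.9% and KLF/SP sites to 1.49%, while DREs peak at 2.75%.

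The DRE, motif 1 and a CTCF site had the highest odds ratios of the 24 motifs against the comparison peaks. The DNA replication-related element (DRE) TATCGATA, bound by DREF, occurred in 168 optimal windows (5.01%) against 1.16% of comparison windows, an odds ratio of 4.51 (3.63 to 5.60, exact adjusted p = 8.95e-38). Motif 1, GGTCACACT, the core promoter site of M1BP, occurred in 2.09% against 0.538% (odds ratio 3.95, 2.86 to 5.46, exact adjusted p = 9.49e-15). A site of the insulator protein CTCF, AGGTGGCGC, was present in 21 optimal windows, 0.627% against 0.245% (odds ratio 2.57, exact adjusted p = 0.00217). Of the 24 motifs fixed in advance, 8 were more frequent and 4 less frequent in optimal windows at adjusted p below 0.05 (Fisher's exact test, Benjamini-Hochberg). The odds ratios of DRE, motif 1 and the CTCF site were 5.14, 5.96 and 2.14 in replicate 1 alone, and 5.23, 3.72 and 3.88 in replicate 3 alone, and 2.85, 2.63 and 5.28 with equal GC content. The last, of the CTCF site, rests on few windows (0.627% against 0.119%) and has a wide interval of 1.81 to 15.4. Within 500 bp of a TSS, DRE stood at 2.71 and motif 1 at 1.84. Against the next-ranked pooled peaks none of these sites was enriched, since those held DRE at 5.60% (odds ratio 0.890, exact adjusted p = 0.764), motif 1 at 3.44% (odds ratio 0.600, exact adjusted p = 0.0124, less frequent at optimal summits) and the CTCF site at 0.763% (odds ratio 0.820, exact adjusted p = 0.911). The CTCF call was also lost against the left flanking windows (0.328%, exact McNemar test, adjusted p = 0.189), within 500 bp of a TSS (1.76, exact adjusted p = 0.525) and in windows of 50 bp to each side (2.42, exact adjusted p = 0.0666).

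The other 5 motifs that were more frequent were the forkhead site TGTTTAC (8.09% against 4.98%, odds ratio 1.68), TATAAA (34.2% against 24.9%, 1.57), the Sox core ACAAT (51.5% against 44.7%, 1.31), the homeodomain site TAATTA (16.3% against 13.4%, 1.25) and the E-box CAGCTG (10.3% against 8.47%, 1.24). Besides the KLF/SP site, the Pho core GCCAT (26.2% against 33.7%, 0.697), the Tead site CATTCC (6.66% against 9.28%, 0.697) and the nuclear receptor half-site AGGTCA (3.55% against 4.44%, 0.792) were less frequent. With comparison windows of equal GC content, none of the 4 less frequent motifs passed the test, and the calls of TATAAA (odds ratio 0.973), ACAAT (1.07) and TAATTA (0.901) were also lost. Against the next-ranked pooled peaks the calls of TGTTTAC (1.18, exact adjusted p = 0.272), CAGCTG (1.02, exact adjusted p = 0.998) and TAATTA (1.18, exact adjusted p = 0.0753) were lost, as were those of GCCAT (0.970), CATTCC (1.00) and AGGTCA (0.920), and within 500 bp of a TSS with equal GC content TGTTTAC stood at 1.15 (exact adjusted p = 0.707). The GAGA factor site GAGAGAG did not pass over all windows (1.17, exact adjusted p = 0.221) and was called with equal GC content (1.82, exact adjusted p = 0.000417) and in windows of 200 bp to each side. The call of CAGCTG was lost in replicate 3 alone (1.10, exact adjusted p = 0.237) and in windows of 50 bp to each side (1.05, exact adjusted p = 0.763), flanking windows held the site at 10.6% on the left and 9.79% on the right (exact McNemar test, adjusted p = 0.895 and 0.664), and with equal GC content its shares were 10.3% and 5.52%. AGGTCA lost its call in those narrow windows (0.780, exact adjusted p = 0.148) and within 500 bp of a TSS (0.868, exact adjusted p = 0.647), as CATTCC did within 500 bp of a TSS (0.884, exact adjusted p = 0.525). The site GAGAGAG was called in replicate 1 alone (1.45) and stood at 0.903 in replicate 3 alone, and it was less frequent at the summit than in the left flanking windows (3.64% against 4.93%, exact McNemar test, adjusted p = 0.0213). Apart from CAGCTG and the CTCF site, the motifs called over all windows were also called against both flanks, in the same direction. Flanking windows were not matched on GC content, so these calls do not set it aside. In windows of 101 bp GC content was 34.9% at optimal summits, 44.0% at 500 bp to the left and 43.9% at 500 bp to the right. The sites of Zelda, AP-1, CREB, GATA factors, Grainyhead, Mef2, Su(Hw), STAT and Su(H) and both CACGTG E-boxes did not pass over all windows. In windows of 50 bp to each side that of Su(H) was called as less frequent (0.600, 0.394 to 0.912, exact adjusted p = 0.0358), as it was against the left flank (1.97% against 2.99%, exact McNemar test, adjusted p = 0.0213) and that of Zelda against the right flank (0.896% against 1.61%, adjusted p = 0.0213). Over distal summits that of Su(Hw) was called as more frequent (2.30, exact adjusted p = 0.0173), which was lost with equal GC content (1.71).

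**Figure D3:**
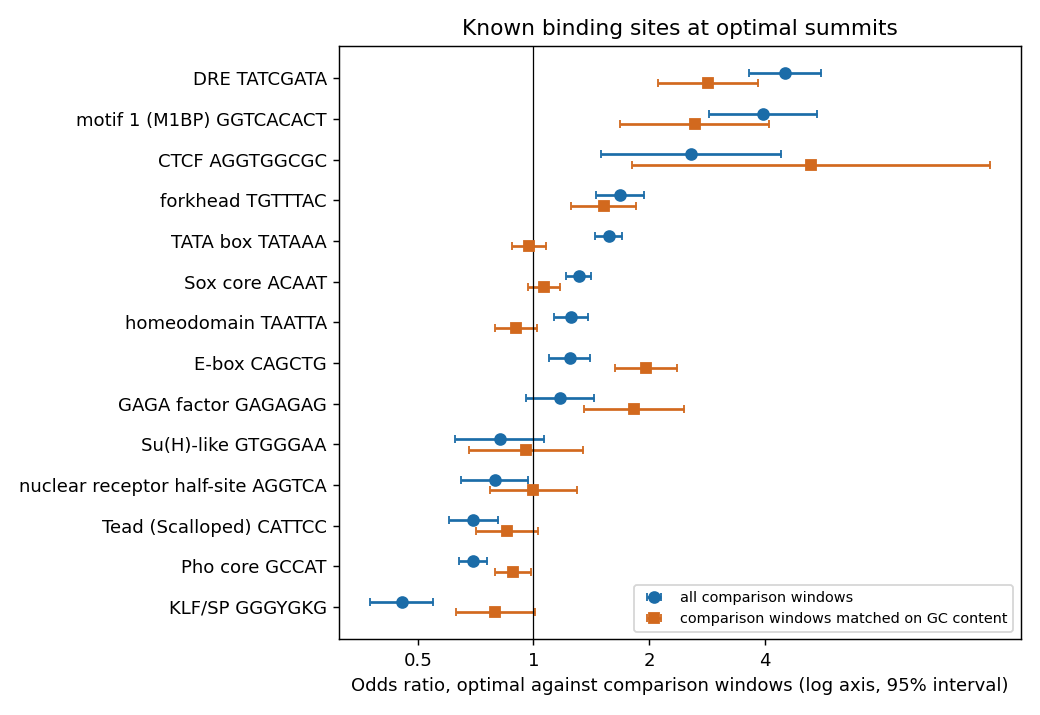
Odds ratio of optimal windows (horizontal log axis, 95% interval bars) against all comparison windows (blue circles) and those matched on GC content (orange squares). Shown is each motif called in at least 1 setting, with flanking windows and distal summits not counted as settings. DRE stands at 4.51 and 2.85, and the KLF/SP site at 0.454 and 0.796.

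Of the 10 leading words in a search of all six-base words, 2 lie within the DRE and 6 within none of the 24 motifs. In optimal windows 497 words were more frequent and 862 less frequent (Fisher's exact test, adjusted p below 0.05). With equal GC content the counts were 194 and 164. Words were not tested near a TSS or against the next-ranked pooled peaks. The highest odds ratios among words in at least 5% of optimal windows were those of CGATAG (12.6% against 5.01%, odds ratio 2.74), ACACTG (in 19.9% of optimal windows), ACAGTG (in 19.0%, odds ratio 2.38) and TATCGA (17.3% against 8.71%, 2.20), followed by ACTATC, TTAAAA, ATCGAT, ACTGTA, AAAATA and AAAAAT, the last at 1.92. TATCGA and ATCGAT lie within the DRE, and CGATAG and ACTATC overlap its ends. ACACTG overlaps the end of motif 1, while AAAATA and AAAAAT can lie within the Mef2 site. ACACTG, ACTGTA and CACTGT, the reverse complement of ACAGTG, overlap one another in sequence. Whether they mark the same sites was not determined. With equal GC content the odds ratios were 2.57 for ACACTG, 2.47 for ACAGTG and 2.40 for CGATAG. Those of ATCGAT, ACTGTA, TATCGA and ACTATC were 1.97, 1.94, 1.80 and 1.76. The words of mostly A and T fell further, TTAAAA to 1.31, AAAATA to 1.21 and AAAAAT to 1.20. Among words in at least 5% of comparison windows the lowest ratio was that of GGAGGA (2.36% against 7.87%, 0.283, and 0.488 with equal GC content).

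Ribosomal protein genes carried optimal peaks at their promoters far more often than other genes. An optimal summit lay within 1000 bp of a TSS for 2848 of 13968 protein-coding genes (20.4%). It did so for 68 of 92 cytoplasmic ribosomal protein genes (73.9%), an odds ratio of 11.3 (7.09 to 18.0, Fisher's exact test adjusted p = 6.71e-27 over 28 lists), and 6.82 among genes with any relaxed promoter peak. The strongest were RpS27 (signal 391, 3R from 25247380 to 25247667), RpL7 (389, 2L from 10200902 to 10201158), RpL34b (326, 3R from 9401180 to 9401527) and RpL14 (312, 3L from 8600814 to 8601062), all within 100 bp of a TSS. Mitochondrial ribosomal protein genes had peaks at 28 of 73 promoters (38.4%, odds ratio 2.44, exact adjusted p = 0.00213), led by mRpL41, mRpS10, mRpS23 and mRpL23. With each peak given to its nearest TSS only, the share was 20.5% against 14.1% and the call was lost (odds ratio 1.57, exact adjusted p = 0.276). Glycolytic genes had peaks at 8 of 12 (odds ratio 7.83, 2.36 to 26.0, Fisher's exact test adjusted p = 0.00309), the strongest at Gapdh2 (signal 526), Hex-A (350), Eno (232) and Ldh (209), and the odds ratio was 11.8 in replicate 1 alone and 5.56 in replicate 3 alone. Beside random lists of equal gene length and TSS number, the glycolysis call was lost (2.95, permutation, adjusted p = 0.241) and the mitochondrial ribosomal ratio was 4.23. Beside genes with any relaxed promoter peak both calls were lost. The mitochondrial ribosomal ratio fell to 1.38 (exact adjusted p = 0.581), while that of glycolysis was 5.51 (1.46 to 20.8, exact adjusted p = 0.0535). Both were also lost for the stronger 50% of the peaks (exact adjusted p = 0.115 and 0.0548).

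Genes of cuticle, chemosensation and seminal fluid carried few peaks, as did transfer RNA genes. Cuticle protein genes had a promoter peak at 1 of 117 (0.855%, Cpr73D; odds ratio 0.0333, 0.00465 to 0.239, Fisher's exact test adjusted p = 1.45e-09), with a ratio of 0.0816 beside random lists of equal gene length and TSS number and of 0.0894 (1 of 24, exact adjusted p = 0.0149) among genes with any relaxed promoter peak. Few peaks were also found at chemosensory receptor genes, 5 of 179 (2.79%, odds ratio 0.111, exact adjusted p = 5.77e-11, the strongest at Gr32a). Seminal fluid and male-specific genes had 2 of 47 (Sfp26Ad and Sfp24F; odds ratio 0.173, Fisher's exact test adjusted p = 0.0127), and the ratio was 0.0852 in replicate 1 alone and 0.0858 in replicate 3 alone. Transfer RNA genes had 21 of 295 (7.12%) against 17.6% of all other genes (odds ratio 0.358, exact adjusted p = 2.56e-06), led by tRNA:Tyr-GTA-1-8. Beside genes with any relaxed promoter peak, the chemosensory call (odds ratio 0.490, exact adjusted p = 0.581) and the seminal fluid call (0.589, exact adjusted p = 0.925) were lost. Beside random lists of equal gene length and TSS number, the seminal fluid (permutation, adjusted p = 0.537) and transfer RNA calls (adjusted p = 1) were lost. For the stronger 50% of the peaks both were lost as well. The seminal fluid ratio was then 0.167 (exact adjusted p = 0.153), close to its main value, and the transfer RNA ratio 0.557 (exact adjusted p = 0.0977). At 250 bp the cuticle, chemosensory and seminal fluid lists had 0 genes with a peak and the transfer RNA ratio was 0.205, and at 2000 bp the ratios were 0.0522, 0.159, 0.206 and 0.546.

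None of the lists of embryonic regulators passed Fisher's exact test against the 20.4% of other genes. Segmentation genes had 1 of 22 (ptc, the Hedgehog receptor; odds ratio 0.186, Fisher's exact test adjusted p = 0.185), mesoderm and muscle regulators 0 of 16 (exact adjusted p = 0.172) and Hox genes 0 of 8 (Fisher's exact test adjusted p = 0.653). Beside random lists of equal gene length and TSS number, of whose members 26.5% had a peak, the mesoderm and muscle list was called (odds ratio 0.0785, permutation, adjusted p = 0.0439), and it stood at 1.01 at 2000 bp and at 0.264 in replicate 3 alone. With 0 of 16 members, the ratio of 0.0785 depends on the constant added to each count. Neural regulators had 2 of 18 (elav and brat), genes of neuronal function 1 of 15 (Syx1A), epidermis and cuticle regulators 1 of 9 (shn) and blood and fat body genes 1 of 12 (ush), with adjusted p values between 0.621 and 0.857 by Fisher's exact test. Cell cycle genes had 8 of 19 (Dp, Cdk1, Cdk4 and fzr strongest; odds ratio 2.84, Fisher's exact test adjusted p = 0.136), and chromatin and Polycomb or trithorax genes 7 of 18 (ph-p, brm, Su(z)12 and Trl strongest; odds ratio 2.49, adjusted p = 0.185). Both of these lists passed in 1 replicate alone, cell cycle in replicate 1 (odds ratio 3.55, exact adjusted p = 0.029) and chromatin in replicate 3 (4.97, exact adjusted p = 0.00385, beside 1.51 in replicate 1). Both also passed at 2000 bp (3.38 and 3.80, exact adjusted p = 0.0357 and 0.0157) and with the nearest TSS only (3.54 and 3.87, exact adjusted p = 0.0374 and 0.0302).

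The remaining lists did not pass either. Genes of trachea and salivary gland had 4 of 10 (fkh, CrebA, eyg and trh), ecdysone response genes 5 of 13 (Eip75B strongest), heat shock genes 5 of 14 (Hsp27 strongest), gut and endoderm genes 3 of 10 (bowl, cnc and lin), circadian clock genes 3 of 11 (sgg, Pdp1 and vri) and glial genes 2 of 9 (moody and loco). Nephrocyte and heart genes, a list chosen because Klf15 is known for its role in nephrocytes, the filtration cells of the fly, had 3 of 14 (cindr, pyd and tin; odds ratio 1.06, Fisher's exact test adjusted p = 1). Proteasome genes had 9 of 48 (Rpn5 strongest), Notch target E(spl) genes 2 of 11, muscle structure genes 3 of 18 (Msp300, sls and Tm1), and small nucleolar and nuclear RNA genes 56 of 306. Their adjusted p values by Fisher's exact test lay between 0.298 and 1. The small nucleolar and nuclear RNA list was called in both directions by other settings, with fewer peaks at 250 bp (0.197, exact adjusted p = 5.56e-08), at 500 bp (0.381, exact adjusted p = 2.42e-05) and for the nearest TSS (0.201, exact adjusted p = 1.20e-07), and with more at 2000 bp (1.97, exact adjusted p = 4.71e-07) and beside random lists of equal gene length and TSS number (2.76, permutation, adjusted p = 0.00112).

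**Figure D4:**
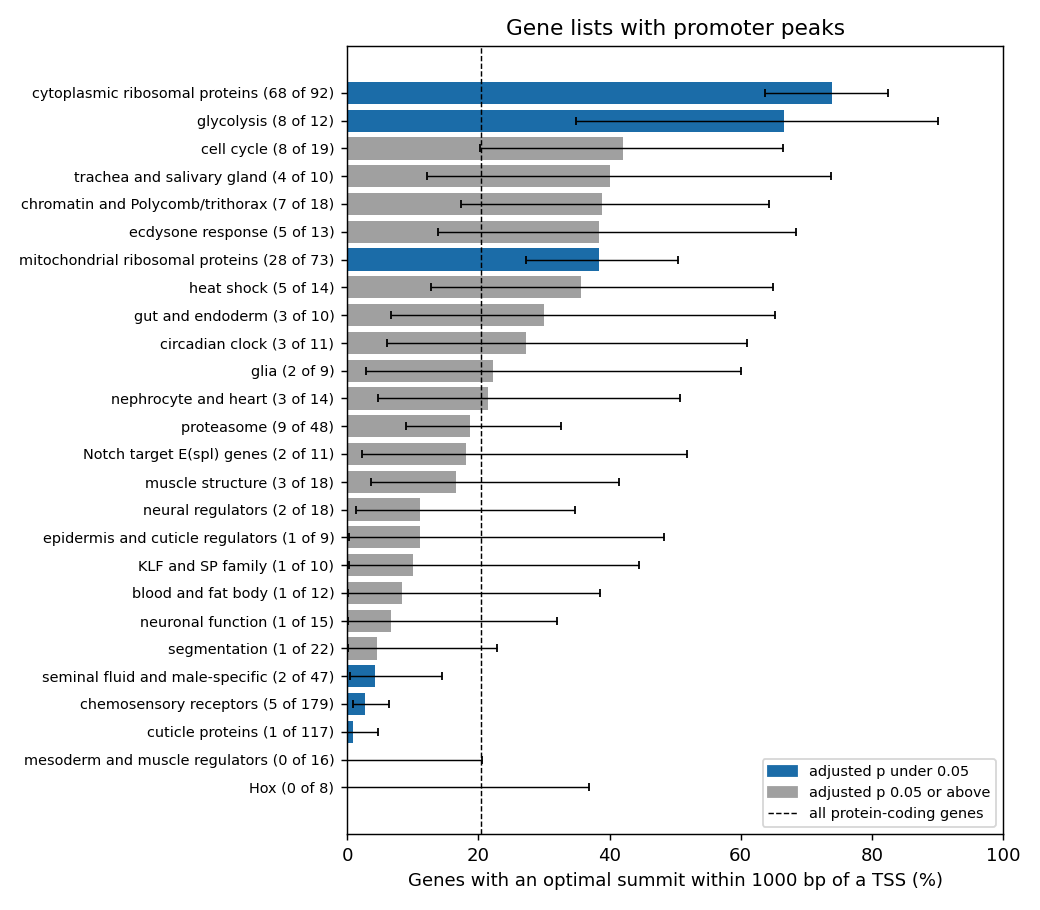
Share of genes (percent, horizontal axis) with an optimal summit within 1000 bp of a TSS in each list of protein-coding genes, with exact 95% binomial intervals as error bars and members with a peak beside each name. Blue bars passed Fisher's exact test at adjusted p below 0.05, and the dashed line marks the 20.4% of all protein-coding genes.

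The arms of chromosomes 2 and 3 and the X held between 23.6 and 27.6 optimal peaks per Mb, and chromosomes 4 and Y fewer. The density was 27.6 peaks per Mb on 2L (95% Poisson interval 25.6 to 29.9), 24.9 on 2R, 25.7 on 3L, 24.3 on 3R and 23.6 on X (21.7 to 25.6). Chromosome 4 had 14 peaks, 10.4 per Mb (5.68 to 17.4), and chromosome Y had 0, which allows up to 1.01 per Mb. Densities are per assembled length. Mappability and the copy number of X and Y in embryos of both sexes were not taken into account. The X had 555 peaks against 2781 on the arms of chromosomes 2 and 3, a ratio of densities of 0.924 (0.842 to 1.01, two-sided exact binomial test p = 0.0894), which did not pass. Relative to genes per arm the ratio was 1.08 (exact p = 0.0948), also not past the threshold.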

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

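No test in this part was chosen after its result was seen. Peaks on heterochromatin and unplaced scaffolds of dm3 entered no comparison of the report, and they numbered 41 in the pooled relaxed list, 37 in that of replicate 1 and 68 in that of replicate 3, all above the 3 that a count of 0 allows. They are weak candidates, since the optimal dm3 set held 0 of them. The dm6 lists held no summit off the arms.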

How the results depend on the processing

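Restriction to windows within 500 bp of a TSS, with or without equal GC content, and the background of genes with any relaxed promoter peak were chosen after the data had been seen. Of the summary results under all alternatives, 52 kept their direction, threshold side or size, while 19 moved, 2 turned and 2 lost a call. Of 211 such values of single motifs and lists, 114 kept a call, 44 lost and 16 gained one, 1 was called the other way (motif 1 against next-ranked peaks) and 36 had none in either. The promoter share kept its direction and call under all 9 alternatives, with odds ratios of 1.37 to 7.04. The peak count was 1675 for the stronger 50%, by construction. The replicate overlap was 67.3% for summits within 100 bp, 68.7% for 50% reciprocal overlap, and 77.6%, 79.2% and 73.1% for the strongest 500, 1000 and 5000 peaks. Leaving out a replicate could not be done for the overlap.

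The KLF/SP odds ratio lost its call with equal GC content (0.796) and with that near a TSS (1), and turned to 1.55 against shuffled windows. Only optimal windows were shuffled, so the last value does not set optimal against comparison peaks. More frequent motifs numbered 2 against next-ranked peaks and 2 near a TSS with equal GC content. Less frequent motifs numbered 0 with equal GC content, 2 against next-ranked peaks, 2 near a TSS and 0 near a TSS with equal GC content. Six-base words numbered 194 more and 164 less frequent with equal GC content. Each replicate alone gave ratios of 0.903 and 1.45 for GAGAGAG, which stood at 0.729 against next-ranked peaks, 0.700 in windows of 50 bp to each side and 0.915 near a TSS. Against next-ranked peaks TATCGATA (0.890), GGTCACACT (0.600), AGGTGGCGC (0.820) and CATTCC (1.00) turned. With equal GC content TAATTA (0.901, near a TSS 0.887) and TATAAA (0.973) turned, and near a TSS also GCCAT (1.01) and ACAAT (0.996).

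Lists with more peaks numbered 6 at 2000 bp, 1 for the stronger 50% and 1 among genes with any relaxed peak; lists with fewer numbered 2 for the stronger 50% and 2 among genes with any relaxed peak. Mesoderm and muscle regulators stood at 1.01 at 2000 bp. Small nucleolar and nuclear RNA genes stood at 0.197 at 250 bp, 0.381 at 500 bp, 0.201 for the nearest TSS and 0.852 among genes with any relaxed peak, against 1.97 at 2000 bp and 2.76 beside matched lists, with calls both ways. The X ratio was 1.08 by genes per arm. The cause was not tested for these changes, other than GC content. Arm lengths of dm3 were not used here, so the dm3 set was set against dm3 pooled peaks per arm. With 2 libraries and no read depth, the number of peaks past the authors' threshold cannot be separated from depth.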

Other observations

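In this part the tests of sites beside the summit, of windows near a TSS, of the 24 motifs at distal summits and of genes with any relaxed promoter peak were chosen after the main values had been seen. Divergent promoters, where neighbouring genes are read in opposite directions from a shared region, were more frequent at optimal than at comparison summits near a TSS, though most optimal summits lay elsewhere. Of 1976 optimal summits within 500 bp of a TSS, 795 (40.2%) had such a pair within reach, against 414 of 3476 comparison summits (11.9%), an odds ratio of 4.98 (4.34 to 5.71, Fisher's exact test p = 2.67e-125). Optimal summits lie closer to TSSs, where pairs fall within reach more easily, but with summits matched on that distance the ratio was 3.59 (3.09 to 4.17), with 40.2% against 15.8%. The side of the TSS was not matched, and 77.5% of optimal summits within 1000 bp of a TSS lay upstream. Position relative to the TSS is therefore not fully set aside. Next-ranked pooled peaks stood in between, at 28.3% of 1595. Examples among the strongest peaks are Chro and Ssl1, whose TSSs are 105 bp apart (3L, 22878984 and 22879089), Art3 and mRpS10 (257 bp), Tcs5 and CHMP2B (224 bp), Fbw5 and CG9147 (134 bp), and Atat and Shc (252 bp, peak at 3L from 9426707 to 9427046). A preference for divergent promoters may thus accompany strong peaks, as a hypothesis found and tested on the same data.

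The genes with the most optimal summits within their bounds were of different lengths, and their counts were not tested against chance. CHES-1-like, a forkhead-type transcription factor gene (X from 7682338 to 7709385), held 10 in 27.0 kb, or 0.370 per kb against 0.0244 per kb over the arms. ush, which encodes a zinc finger cofactor of GATA proteins (2L from 476220 to 540560), held 10 (0.155 per kb), among them the peak of rank 3 near cbt, and sbb (2R from 18278198 to 18357296) also held 10 (0.126 per kb). Raf, a kinase gene of receptor tyrosine kinase signalling, held 8 (0.165 per kb), as did shn (0.137 per kb) and RapGAP1 (0.0986 per kb), and Eip75B, an ecdysone-induced nuclear receptor gene, held 7 (0.0615 per kb). The highest count was in lncRNA:CR44357 (14 in 239 kb, 0.0585 per kb), which overlaps CG1677 (12 peaks, 0.0962 per kb). kirre, an adhesion protein gene of myoblasts and nephrocytes, held 9 in 394 kb, or 0.0228 per kb, below the density over the arms.

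KLF/SP sites were rarer at optimal summits (3.79% against 7.99%), although the factor is a KLF protein. Restriction to summits within 500 bp of a TSS did not remove the difference, with an odds ratio of 0.567 (0.434 to 0.741). For this site summits were not matched on distance to the TSS, so position within promoters stays open. GC content is a candidate explanation, because with equal GC content the ratio was 0.796 (0.627 to 1.01), and 1.00 (0.718 to 1.39) near a TSS. Summits placed beside the bound site stay open, since 150 to 350 bp away the ratio was 1.07 (0.966 to 1.18) over all windows and 0.955 (0.841 to 1.08) with equal GC content, intervals that leave room for a small excess, and windows of 101 bp held the site at 5.40% against 4.33% at 300 bp to the left, 3.49% against 3.99% at 200 bp to the left and 5.04% against 4.53% at 300 bp to the right. Since the design has 1 group and no anti-GFP list of another factor was analysed here, no biological explanation was tested for this or the next patterns.

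DRE and motif 1 sites were more frequent at optimal summits, with either site in 6.96% against 1.61% (odds ratio 4.56, 3.79 to 5.49). Promoter position lowered the ratio to 2.58 (2.09 to 3.18), distance to the TSS to 1.82 (1.46 to 2.29) and equal GC content to 2.91 (2.25 to 3.75), so that none of these alone accounts for the whole. Each may account for part, and near a TSS with equal GC content DRE stood at 1.89 (1.44 to 2.47) and motif 1 lost its call (1.60, exact adjusted p = 0.163). Next-ranked pooled peaks gave odds ratios of 0.890 and 0.600, so the excess holds against the comparison peaks, which may include background, and not against these. At distal summits no excess of DRE was seen (0.379% against 0.523%, 0.724, 0.260 to 2.01, and 0.442, 0.136 to 1.44, with equal GC content), and motif 1 was in 2 of 1056 (1.58, 0.350 to 7.15).

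Ribosomal protein genes stood out by 68 of 92 promoters with a peak. Random lists of equal gene length and TSS number gave 14 to 29 (central 95%), so 68 lies outside. Among genes with any relaxed promoter peak the odds ratio was 6.82 (4.17 to 11.1), so a wider detection of these promoters is not the whole cause. How strongly these genes are transcribed in the embryo was not analysed here and stays open, as a possible explanation that these lists cannot test.

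Further hypotheses on KLF/SP sites gave no support. Among 1056 distal optimal summits, over 1000 bp from a TSS, the site was present in 3.79% against 5.21% of distal comparison summits of equal GC content (odds ratio 0.717, 0.472 to 1.09), so an enrichment away from promoters was not seen. The strongest and weakest 837 optimal peaks had the site in 3.35% and 4.30%, a difference of -0.956 percentage points (Fisher's exact test p = 0.372). Against all 9183 distal comparison summits the sites of CTCF (0.758% against 0.229%, odds ratio 3.33, exact adjusted p = 0.0223), Su(Hw) (2.30, exact adjusted p = 0.0173) and forkhead factors (1.72, exact adjusted p = 0.000156), TATAAA (1.53) and ACAAT (1.35) were more frequent. The KLF/SP site (0.438), GCCAT (0.604) and CATTCC (0.644) were less frequent. With equal GC content, which left 1056 comparison windows, none of the 24 passed, with CTCF at 2.68 (0.709 to 10.1), Su(Hw) at 1.71 (0.780 to 3.76) and forkhead at 1.43 (1.02 to 2.02), and 2 had an unadjusted p below 0.05, forkhead (exact p = 0.0468) and GCCAT (0.789, exact p = 0.0183), so that intervals are wide and an excess is not excluded.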
